A study of Rattus norvegicus with 10 samples.

How the data were processed

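Kidney RNA of Wistar rats was measured by RNA-seq in 10 libraries, 5 from rats given 0.9 percent NaCl (saline) and 5 from rats given silica nanoparticles (SiNP) as an endotracheal drip at 6.0 mg per kg per week, per the labels. The labels give the strain, the tissue, the treatment and a number from 1 to 5 within each group. They give no sex, batch, collection time or part of the kidney. They do not state that the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may in part be technical. RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit, per the labels' protocols.

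The authors deposited a table of counts per gene and a table of FPKM per gene. The submitters' processing notes name HISAT2 2.0.5, StringTie 1.3.3b, featureCounts 1.5.0-p3 and the genome build rn6. The counts are whole numbers that sum to between 16151917 and 19154851 per library, with no normalization, and per the file headers each gene carries its coordinates, length and biotype. The deposited FPKM equal the count divided by the gene length and by a single scaled library size per sample, as worked out from the values. That size was 0.82 to 1.12 times the library's total count, so the FPKM already hold a scaling between libraries. Counting strand is not given in the sources used here, so overlapping and antisense genes cannot be told apart. Genes that share sequence with near copies, such as globins, metallothioneins and ribosomal proteins, are uncertain.

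The table holds 34413 genes, of which 11388 had no count in any library. The low-count filter filterByExpr left 15346 genes, which were scaled by TMM and tested by the quasi-likelihood F-test of edgeR 4.0.16 with robust estimation in R 4.3.3. The model held the group alone and used all 10 libraries. Adjusted p is the Benjamini-Hochberg value over the genes tested, with a threshold of 0.05. Fold changes are SiNP over saline, with a standard error (SE) and a 95% interval from the same fit. CPM values are normalised by the TMM-scaled library size. Of the genes in the table, 1868 have no symbol. The tested genes include 1141 loci whose identifier marks them as new loci and not as known genes. The common biological coefficient of variation was 0.383.

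Gene lists were fixed before the data were examined. They were UPR chaperones and ERAD, the PERK-ATF4-CHOP branch, apoptosis, kidney injury, NRF2 and oxidative stress, inflammatory cytokines and NF-kB, interferon response, extracellular matrix and fibrosis, fatty acid oxidation and PPARA targets, cholesterol synthesis, oxidative phosphorylation, autophagy and lysosome, heat shock proteins, cell cycle, circadian clock and immediate early genes. Markers of cell types were listed for proximal tubule, loop of Henle, distal tubule and collecting duct, inner medulla and urothelium, podocyte, endothelial, mural and fibroblast, immune, erythroid, adipocyte, adrenal and skeletal muscle cells. Y-linked genes, the mitochondrial genome and ribosomal proteins completed the set. Both UPR lists were also merged into the unfolded protein response list. Of 552 listed entries, 522 matched a symbol in the table, 14 matched through an older symbol in a RefSeq gene table of the assembly GRCr8, used for names alone, and 16 matched nothing. The ribosomal list was taken by symbol pattern, which also took 10 kinases of the Rps6k family. Lists with at least 3 tested members, 29 in all, were tested with camera of limma 3.58.1 on the edgeR fit, with its preset inter-gene correlation of 0.01. The same test with an estimated correlation and the fry test stand beside it. A score per library was the mean over a list of log2(CPM + 1) centred on each gene's mean, tested between groups by a two-sided exact permutation test over the 252 assignments, whose smallest p is 0.00794. Where many lists were tested, p was adjusted over them by the Benjamini-Hochberg method.

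The genes named in the text follow a rule fixed before the data were examined. It takes the 10 highest and 10 lowest fold changes among called genes whose groups do not overlap, with a mean of at least 1 CPM and a symbol that is not a clone name, and fills each side with the smallest unadjusted p. It adds up to 4 members per list with the smallest unadjusted p. It always adds Hspa5, Ddit3, Atf4, Atf6, Xbp1, Ern1, Eif2ak3, Casp12, Bax, Bcl2, Havcr1 and Lcn2. Some genes that the rule takes are not reported here. Genes named outside the rule are marked as such.

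Alternatives fixed in advance were DESeq2 size factors and upper-quartile scaling in edgeR, the Wald test of DESeq2 1.42.0, limma voom with sample quality weights, no filter, a filter of at least 1 CPM in at least 5 libraries, the replicate number as a block, each library left out in turn, and limma on log2(FPKM + 1) with and without a minimum mean FPKM of 1, and limma on log2(FPKM + 0.1) with that minimum. For list scores they were a pseudocount of 0.1 and FPKM in place of CPM. For lists other than the unfolded protein response and apoptosis, the estimated correlation was the single alternative fixed in advance for camera, and the others were added after seeing the data. Alternatives added after seeing the data for all results were a sex term, fits without the 2 libraries that hold Y-linked reads, fits without the 3 libraries poor in inner medulla transcripts, the inner medulla score as a covariate, fits without mitochondrial genes and a fit without robust estimation. The inner medulla score is the mean log2 CPM of those members of the inner medulla and urothelium list with a mean above 20 counts, and libraries below 2 were called poor.

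The fits were tested on simulated data with 200 genes changed. They were drawn from the real means and library sizes and from the dispersions per gene that edgeR estimated. In this simulation of the SiNP and saline comparison, edgeR recovered 80.3% of the genes changed 4-fold, 20.9% of those changed 2-fold and 1.49% of those changed 1.5-fold, among 15150 genes tested, with 1 false call. DESeq2 recovered 89.4%, 38.8% and 11.9%, among 15346 genes, with 35 false calls in 128. With the 66 tested members of the unfolded protein response list raised 1.5-fold in simulated counts, camera gave an adjusted p of 2.3e-45, and of 2.2e-06 with an estimated correlation, among 15164 genes. The simulated genes were independent, which real genes are not. As the dispersions came from edgeR, the simulation may favour edgeR over DESeq2.

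A chi-square of counts over genes, per degree of freedom, was 55.4 to 211 for pairs of libraries of a group, so none agreed within sampling noise and all 10 were counted. Cells of the NRK-52E line, a rat kidney cell line that the series title also names, were not analysed here.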

Results

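The series was designed to find molecular mechanisms of kidney toxicity of silica nanoparticles, and its title names apoptosis and the unfolded protein response. RNA-seq counts were compared between 5 kidney libraries of saline rats and 5 of rats given silica nanoparticles (SiNP). Total counts per library ran from 16151917 to 18699151 in saline and from 16558809 to 19154851 in SiNP (two-sided exact permutation p = 0.294). The mitochondrial genome took 21.4% ± 7.14 of the counts in saline and 16.9% ± 3.61 in SiNP (SD, n = 5 each, two-sided exact permutation p = 0.246). Libraries within each group differed in sex-linked and regional transcripts. Saline 5 and SiNP 5 alone held Y-linked counts, and saline 1, SiNP 2 and SiNP 4 were poor in inner medulla transcripts.

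The gene called between the groups belongs to the circadian clock, the feedback loop that times daily transcription. Cry1, a repressor of that loop, fell to 7.64 ± 1.62 CPM in SiNP (SD, n = 5) from 27.1 ± 5.06 CPM in saline (SD, n = 5). It was the single gene called among the 15346 tested (log2 fold change -1.83, SE 0.19, edgeR adjusted p = 0.0156). The saline libraries lay between 20.5 and 34.1 CPM and all 5 SiNP libraries between 5.89 and 9.48 CPM. Cry1 (ENSRNOG00000006622) lies on chromosome 7 of rn6 from 24534615 to 24634097 on the plus strand. Its fold change stayed between -1.91 and -1.72 when any 1 library was left out, but the call held in only 3 of these 10 fits, with adjusted p up to 0.107. It ended without saline 2, 4 or 5 (adjusted p = 0.0850, 0.0640 and 0.0616) and without SiNP 1, 2, 3 or 4 (0.0625, 0.0586, 0.107 and 0.0570). Without both libraries with Y-linked counts adjusted p was 0.0569, and without the 3 libraries poor in inner medulla 0.208, at log2 fold changes of -1.93 and -1.70.

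Of the 18 tested clock genes, 4 passed when p was adjusted over the list alone, against 1 over all genes. Nr1d1, which encodes the repressor REV-ERB alpha, was at 68.4 ± 28.7 CPM in SiNP (SD, n = 5) and 22.3 ± 9.67 CPM in saline (SD, n = 5), a log2 fold change of 1.62 (SE 0.38). Its paralog Nr1d2 had a log2 fold change of 1.03 (SE 0.22), and Nfil3, a repressor of clock output genes, one of -0.84 (SE 0.26). Adjusted over the list alone, p was 0.00854 for Nr1d1, 0.00521 for Nr1d2 and 0.0372 for Nfil3 in edgeR. For these 3 genes the groups did not overlap, and over all genes their adjusted p from edgeR was 0.508 to 0.513. Per2, named outside the rule, had a log2 fold change of -0.77 (SE 0.27) and did not pass over the list alone. With a sex term, added after seeing the data, Nr1d2 was called over all genes (log2 fold change 1.06, adjusted p = 0.0356), and without both libraries with Y-linked counts its adjusted p was 0.0569. Camera, which tests movement of a whole list one way, gave no call (adjusted p = 0.726), with 9 members higher and 9 lower, a median log2 fold change of -0.03 and a mean of 0.01. The fry test for change in either direction gave an adjusted p of 2.1e-04, and passed for the inflammatory list as well (adjusted p = 0.00389).

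**Figure D1:**
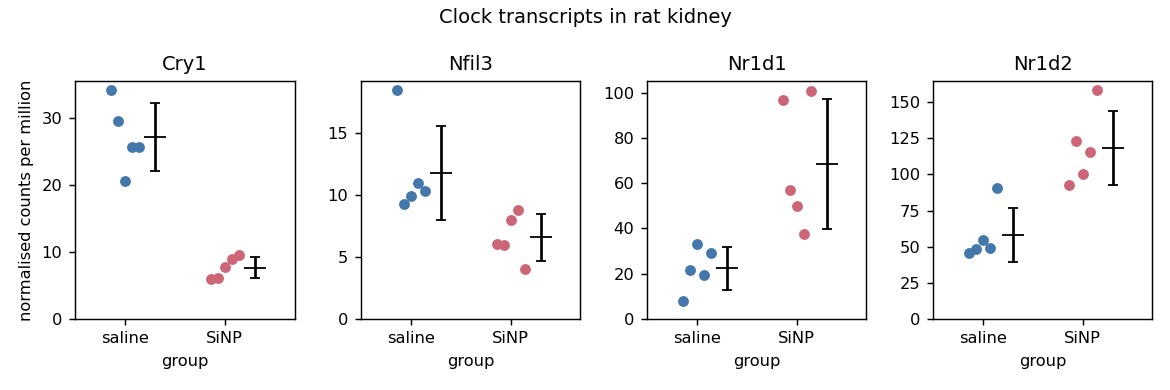
Normalised counts in CPM (vertical axes, each from 0) of Cry1, Nfil3, Nr1d1 and Nr1d2 in saline and SiNP kidney libraries (horizontal axes). Points are libraries and bars give the mean ± SD of 5. Every SiNP library is below every saline library for Cry1 and Nfil3, and above for Nr1d1 and Nr1d2.

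No other gene was called by edgeR: 0 genes passed as higher and 1 as lower, and that gene changed at least 2-fold. At an unadjusted p under 0.05 there were 1374 genes, 690 higher and 684 lower, against 767 expected on average by chance. That number can vary widely, as genes are not independent. Groups did not overlap for 198 genes, 1.29% of those tested, where chance gives 0.794%. Limma voom called 0 higher and 1 lower, and the Wald test of DESeq2 called 81 genes, 60 higher and 21 lower. Without saline 1 edgeR called 2 genes, 1 of them higher, and without SiNP 5 it called 3, of which 2 were higher. The calls of DESeq2 included Il1b, which encodes the cytokine interleukin 1 beta, Nr1d1, Nr1d2, the collagen gene Col3a1 and the sodium cotransporter genes Slc5a12 and Slc5a2. In simulated counts, drawn with dispersions that edgeR estimated, DESeq2 gave 35 false calls among 128.

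The genes with the smallest unadjusted p on the higher side were not called by edgeR, each with an adjusted p of 0.508. They were MGC108823, Il1b, Ppt1, Nr1d2, Ddx60, Apaf1, Gpm6b, Ighm, Pdgfra and Cyp2e1, with log2 fold changes from 0.60 in Ppt1 to 1.80 in Ighm. Il1b was at 3.10 ± 0.95 CPM in SiNP and 1.10 ± 0.21 CPM in saline (SD, n = 5 each). Ighm, the heavy chain of immunoglobulin M, was at 20.7 ± 11.2 CPM in SiNP and 5.97 ± 0.64 CPM in saline (SD, n = 5 each), with SiNP 5 at 4.36 CPM, below all saline libraries. Pdgfra, a receptor of fibroblasts, had a log2 fold change of 1.01 (SE 0.24). On the lower side, Gm9905, Lpcat4, Ccdc92, Rnf126, Etnk2, Fam109a, Cml5, Mplkip and Fam20c were likewise not called, with log2 fold changes from -1.05 in Etnk2 to -0.61 in Mplkip.

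The unfolded protein response, which raises chaperones of the endoplasmic reticulum when proteins misfold, was the process named in the title. Of 66 tested members of its list, 33 were higher and 33 lower in SiNP, and 0 passed in edgeR over all genes or adjusted over the list alone, nor did DESeq2 call any of them. At an unadjusted p under 0.05 there were 12 members, 2 higher and 10 lower. The higher ones were Ssr1 (log2 fold change 0.45, SE 0.14) and Casp12 (1.27, SE 0.43). The lower ones included Syvn1, a ubiquitin ligase of endoplasmic reticulum degradation (-0.49, SE 0.12), Manf (-0.64, SE 0.17), Sdf2l1 (-0.84, SE 0.26), Asns (-0.88, SE 0.30) and Chac1 (-1.31, SE 0.49). Without saline 1 Asns was at -0.56. Camera gave an adjusted p of 0.437 in the lower direction, and of 0.883 with an estimated correlation. The median log2 fold change was -0.02 and the mean -0.05.

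Transcripts of the sensors and main targets of the response did not pass the test, and RNA counts do not measure the activity of the proteins. Hspa5, the chaperone BiP (ENSRNOG00000018294, chromosome 3, 13838304 to 13842762), was at 555 ± 77.0 CPM in SiNP and 667 ± 157 CPM in saline (SD, n = 5 each). Its log2 fold change of -0.26 had a 95% interval from -0.67 to 0.14, and without saline 1 it was -0.14. Ddit3, the transcription factor CHOP, had -0.09 with an interval from -0.62 to 0.45. Atf4 had 0.02, Atf6 0.29, Ern1 0.20, Eif2ak3 -0.18 and Xbp1 -0.31, and the intervals of these 5 genes all held 0. Without SiNP 2 Atf6 was at 0.04. The UPR chaperones and ERAD list (adjusted p = 0.437, median 0.00, mean -0.05) and the PERK-ATF4-CHOP list (adjusted p = 0.730) were not called by camera.

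**Figure D2:**
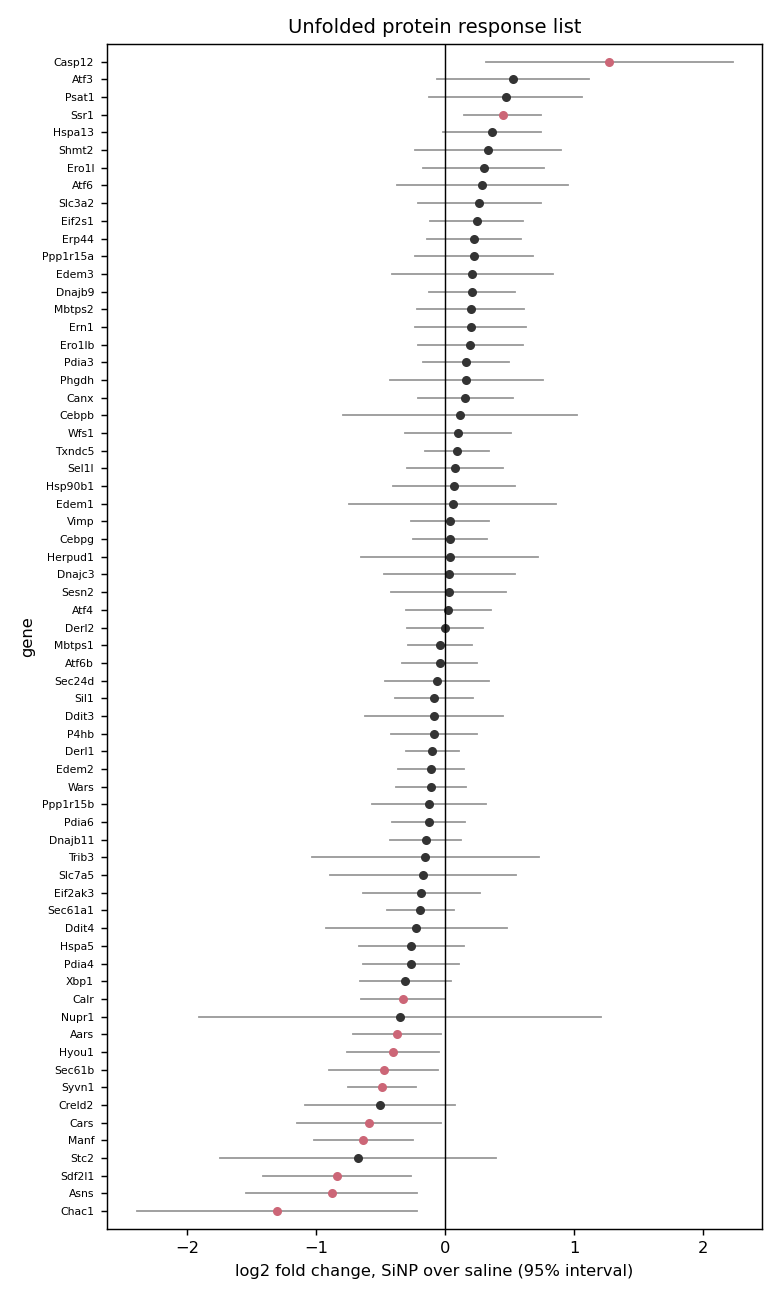
Log2 fold change of SiNP over saline (horizontal axis) for the 66 tested genes of the unfolded protein response list (vertical axis, in order of fold change). Points are edgeR estimates, lines are 95% intervals, and the 12 coloured points have an unadjusted p under 0.05. Of these, 10 lie below 0 and 2 above.

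Of 38 tested apoptosis genes, 18 were higher and 20 lower, and camera gave no call (adjusted p = 0.790). The list's median log2 fold change was -0.02 while its mean was 0.06 and its test pointed higher. Over the list alone 1 gene passed, Apaf1, the scaffold of the apoptosome, and over all genes 0 passed in edgeR, where 7 of the list had an unadjusted p under 0.05. DESeq2 called Apaf1 alone in this list. Apaf1 was at 10.5 ± 2.15 CPM in SiNP and 5.80 ± 0.80 CPM in saline (SD, n = 5 each), a log2 fold change of 0.86 (SE 0.19). Casp12 and Fas, a death receptor, had log2 fold changes of 1.27 and 1.02 at means under 4 CPM in both groups, and Tnfsf10 one of 0.54. The pro-apoptotic gene Bax had -0.50 (SE 0.22) and the anti-apoptotic gene Bcl2 -0.17 (SE 0.35). The counts gave no call for the tubular injury markers Havcr1 (0.39, SE 0.70) and Lcn2 (-0.11, SE 1.11), or for the kidney injury list (adjusted p = 0.730). C3, a complement component in that list, had a log2 fold change of 1.56 (SE 0.45).

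With its preset correlation, camera called 9 of 29 lists, 7 higher and 2 lower, and 0 with an estimated correlation. The extracellular matrix and fibrosis list had 17 of 19 members higher and a median log2 fold change of 0.58 (camera adjusted p = 5.2e-08, and adjusted p = 0.727 with an estimated correlation). Over the list alone 8 genes passed, all higher. Col3a1 was at 62.7 ± 46.0 CPM in SiNP and 14.8 ± 6.23 CPM in saline (SD, n = 5 each), a log2 fold change of 2.08 (SE 0.51). Col6a1 and the matrix protease gene Mmp2 had 1.77 and 1.25. SiNP 5, which held Y-linked counts, had 14.3 CPM of Col3a1, within the saline range. Without SiNP 5 the list was called with an estimated correlation as well (camera adjusted p = 0.0414). This was the only such call among the 10 fits without 1 library, where adjusted p ran up to 0.952. SiNP 5 had the lowest matrix score of the SiNP libraries (-0.55, the others 0.20 to 0.68). Leaving it out was therefore bound to raise the difference.

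Immune cell markers had 15 of 17 members higher and a median of 0.76, among them Ptprc, the leukocyte antigen CD45 (0.93, SE 0.28), Itgam, Csf1r and Cd4. Camera gave this list an adjusted p of 7.6e-06, and an adjusted p of 0.727 with an estimated correlation. In edgeR 0 of its members passed, over all genes or adjusted over the list alone, where 7 had an unadjusted p under 0.05, and DESeq2 called 0. The same counts of 0 held for the interferon, endothelial, fatty acid oxidation, mitochondrial genome and ribosomal protein lists, where 5, 1, 6, 1 and 3 members had an unadjusted p under 0.05. Interferon response genes were higher in 22 of 23 cases, with Ifit2, Mx2, Psmb8 and Ifit3 at log2 fold changes of 0.67, 0.90, 0.87 and 0.73 (adjusted p = 3.9e-05, and adjusted p = 0.883 with an estimated correlation). Of 18 inflammatory and NF-kB genes 13 were higher, and Il1b passed over the list alone (adjusted p = 3.2e-04 for the list, and adjusted p = 0.727 with an estimated correlation). Ptgs2 and Cxcl9 had log2 fold changes of 1.21 and 1.01, and without SiNP 1 the list was not called (adjusted p = 0.0579). The endothelial list was higher in 8 of 9 members, led by Emcn at 0.60 (adjusted p = 0.0201, and adjusted p = 0.883 with an estimated correlation), and this call ended without saline 1 or 3 (adjusted p = 0.0552 and 0.167) or SiNP 1 or 2 (0.296 and 0.105). The difference in score, the mean log2 deviation per library, went from 0.37 to 0.22 for the interferon list without saline 1, and from 0.36 to 0.20 for the endothelial list without saline 3.

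Proximal tubule markers and fatty acid oxidation genes were highest in SiNP 2 and SiNP 4, which were poor in inner medulla transcripts, as was saline 1. Of 20 proximal tubule markers 16 were higher (adjusted p = 0.0101, and adjusted p = 0.883 with an estimated correlation), and 4 passed over the list alone: Slc5a12, Slc6a19, Slc5a2 and Slc4a4, transporters of the early proximal tubule. Slc5a2, the glucose transporter SGLT2, was at 236 CPM in SiNP 2 and 91.5 CPM in SiNP 4, and at most 5.75 CPM in the other 8 libraries. The list's call ended without saline 4, SiNP 2 or SiNP 5 (adjusted p = 0.0759, 0.161 and 0.0585), and without the 3 libraries poor in inner medulla (0.440). Fatty acid oxidation and PPARA targets were higher in 21 of 24 genes (adjusted p = 3.1e-04, and adjusted p = 0.883 with an estimated correlation). Hadhb and Cyp4a1 had log2 fold changes of 0.60 and 2.10, with Cyp4a1 at 0.81 without SiNP 2, and without the 3 libraries poor in inner medulla the list had an adjusted p of 0.0604. Without SiNP 2 the difference in score went from 0.71 to 0.34 for proximal tubule markers and from 0.46 to 0.24 for the fatty acid list. In the NRF2 list (camera adjusted p = 0.283, 0.0361 without SiNP 3, and adjusted p = 0.769 without SiNP 3 with an estimated correlation), Hmox1 and the metallothionein gene Mt1 passed over the list alone, with log2 fold changes of 1.69 and 2.55. Mt1 stood at 979 CPM in SiNP 2 and 423 CPM in SiNP 4, and between 40.8 and 118 CPM elsewhere. Gpx3 and Keap1, which did not pass, had 2.42 and -0.50. Without SiNP 2 Mt1 was at 1.64 and Gpx3 at 1.45.

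All 13 mitochondrial genome genes were lower, with a median log2 fold change of -0.49 (adjusted p = 0.00121, and adjusted p = 0.883 with an estimated correlation), and this call ended without saline 2 (adjusted p = 0.142), the library with the largest mitochondrial share. Without it the difference in score was -0.22, against -0.44 with all libraries. Ribosomal protein genes were lower in 67 of 93 cases with a median of -0.17 (adjusted p = 0.0101, and adjusted p = 0.883 with an estimated correlation), a call that ended without saline 2 or 4 (adjusted p = 0.187 and 0.477) or SiNP 2 or 5 (0.273 and 0.0604). The ribosomal difference in score was -0.12 with all libraries, -0.06 without saline 2, -0.04 without saline 4, -0.05 without SiNP 2 and -0.19 without saline 3.

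**Figure D3:**
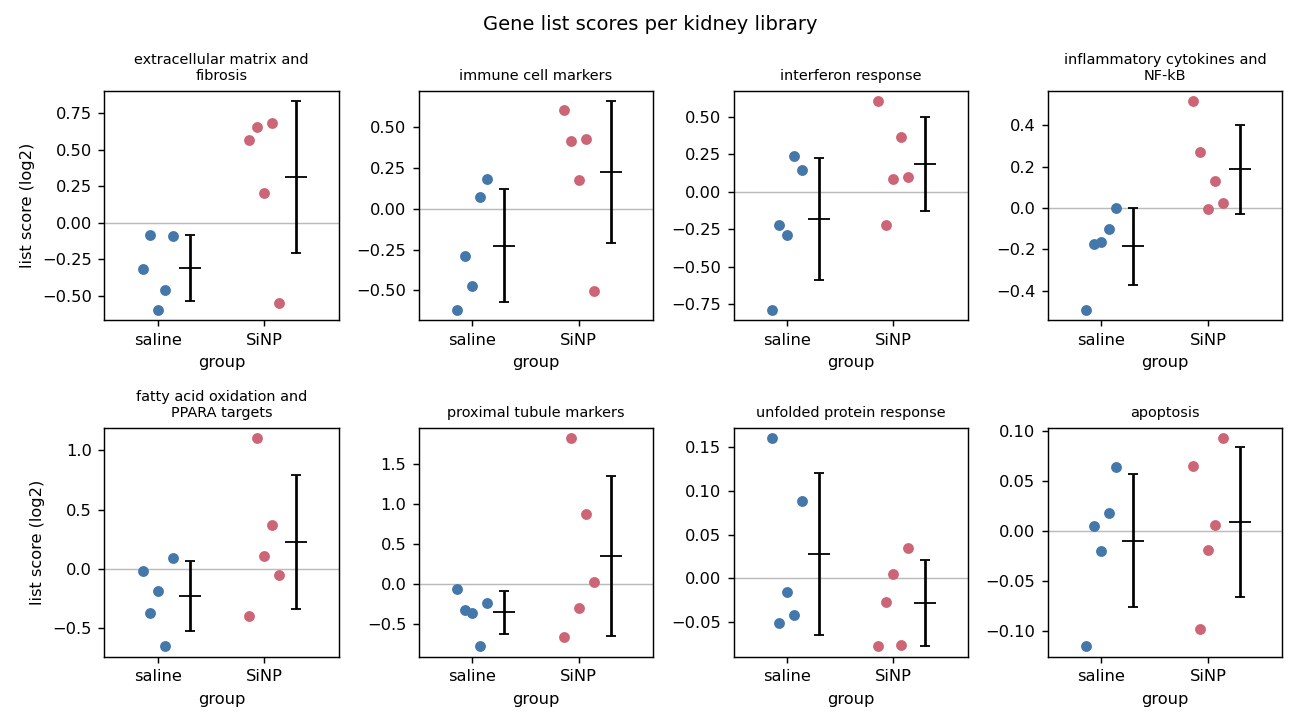
List scores (vertical axes, mean log2 deviation from each gene's mean) of 8 gene lists in saline and SiNP kidney libraries (horizontal axes). Points are libraries and bars give the mean ± SD of 5. Scores of the inflammatory list lie between -0.01 and 0.52 in SiNP and between -0.49 and -0.00 in saline, and SiNP 5 lies at -0.55 in the matrix list.

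Scores per library, which keep the correlation between genes, gave 0 of 29 lists after adjustment. The smallest exact p is 0.00794, and a call needs at least 5 lists at it, or more lists at a larger p. Before adjustment, 2 lists lay under 0.05 in the exact permutation test. The inflammatory score was higher by 0.37 (exact p = 0.0159, adjusted p = 0.460), with all 5 SiNP libraries above the saline median. The matrix score was higher by 0.62 (exact p = 0.0476, adjusted p = 0.649), with 4 of 5 SiNP libraries above the saline median.

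The remaining lists were not called by camera. Adjusted p was 0.154 for immediate early genes, 0.205 for mural and fibroblast markers, 0.206 for erythroid markers, 0.336 for distal tubule and collecting duct markers, 0.412 for cholesterol synthesis and 0.437 for podocyte markers and for the cell cycle. It was 0.730 for loop of Henle and adipocyte markers, 0.853 for inner medulla and urothelium markers, and 0.957 for oxidative phosphorylation, autophagy and lysosome, and heat shock proteins. Adrenal markers had 1 tested member, and skeletal muscle markers and Y-linked genes had 0, too few for a test. Pdgfra passed when adjusted over the mural and fibroblast list alone. The median and the test differed in sign for inner medulla, autophagy and heat shock lists. Leaving out 1 library, an alternative chosen for these lists after seeing the data, gave a call higher for cholesterol synthesis without SiNP 2 (adjusted p = 0.0288), for immediate early genes without SiNP 2 or 4 (0.0288 and 0.00351) and for podocyte markers without saline 1 (0.0142). The same held for mural and fibroblast markers without saline 2 or SiNP 5 (0.0212 and 0.0116) and for erythroid markers without saline 2 (0.0490). With an estimated correlation 0 of these calls held: in fits without 1 library the lowest adjusted p was 0.696 for cholesterol synthesis and erythroid markers, 0.774 for immediate early genes, 0.858 for podocyte markers and 0.705 for mural and fibroblast markers.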

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

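All tests of explanations in this part were chosen after the results had been seen. Single libraries stood far from the other 4 of their group by Dixon's ratio (the gap to the nearest library over the range, limit 0.71), where chance gives about 1 in 20. The ratio was beyond the limit for 15 of 170 gene groups, 3 of 58 list scores and 0 of 8 library measures.

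SiNP 2 stood above the other SiNP libraries in Slc4a4 (688 CPM against 10.9 to 94.0, ratio 0.877), Cyp4a1 (395 CPM, ratio 0.792), Slc5a12 (419 CPM, ratio 0.791) and Bcl2 (4.04 CPM, ratio 0.746). SiNP 1 was highest in the adipocyte score (1.84, ratio 0.747) and the distal tubule and collecting duct score (0.23, ratio 0.828), and SiNP 4 lowest in Mplkip (13.6 CPM, ratio 0.771). Saline 3 was lowest in the endothelial genes Emcn (30.8 CPM, ratio 0.759), Tek (25.8 CPM, ratio 0.713) and Flt1 (17.3 CPM, ratio 0.752). Saline 5 was highest in Nr1d2 (90.8 CPM, ratio 0.807), Ptprc (9.74 CPM, ratio 0.867) and Rps6kl1 (3.08 CPM, ratio 0.754) and lowest in the autophagy and lysosome score (-0.16, ratio 0.723). Saline 1 was highest in Nfil3 (18.5 CPM, ratio 0.820) and Vnn1 (43.0 CPM, ratio 0.769) and lowest in Keap1 (56.8 CPM, ratio 0.856). Saline 2 was highest in Mt-nd4 (5925 CPM, ratio 0.837).

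The first pattern is the higher proximal tubule markers in SiNP, for which a candidate explanation is more cortex in SiNP 2 and SiNP 4. Without the 3 libraries poor in inner medulla transcripts (saline 1, SiNP 2 and SiNP 4), the list's median log2 fold change was 0.16 (quartiles -0.10 to 0.44), against 0.52 (quartiles 0.03 to 1.85) with all libraries, and camera's adjusted p was 0.44 in this smaller fit. With the inner medulla score as a covariate, whose group means lay close together (3.26 in saline and 3.11 in SiNP), the median was 0.45 and the mean 0.72 against 1.35, and camera called the list (adjusted p = 0.00870), but not with an estimated correlation (adjusted p = 0.755). Saline 1 lacked inner medulla transcripts too, yet had 3.72 CPM of Slc5a2, against 236 and 91.5 CPM in SiNP 2 and SiNP 4. The median fell in both fits, strongly without the 3 libraries and little with the covariate. SiNP 2 and SiNP 4 had the highest scores of this list (1.82 and 0.88, the others at most 0.03). Leaving them out was thus bound to lower the group difference whatever its cause, and that fit decides nothing. More cortex stays open, as does an effect of the treatment, which was not tested.

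The second pattern is the higher medians of the matrix and immune lists in SiNP, where 7 of 100 splits of the 10 libraries gave the matrix list as small a camera p as the real one, so chance is not excluded, and the smallest p of another split was 1.0e-15 against 1.8e-09. Without the 3 libraries poor in inner medulla, the immune median kept 0.60 of its value, the matrix median went from 0.58 to 0.66 and its mean from 0.80 to 0.56, and camera called both (adjusted p = 3.4e-04 for matrix and 0.0137 for immune). The matrix score difference fell from 0.62 to 0.38 and the immune one from 0.45 to 0.22 (exact p = 0.343 and 0.600), and with an estimated correlation neither list was called (0.908 for both), while with the inner medulla score as a covariate the medians were 0.59 (0.58 without it) and 0.85 (0.76), so the part of the kidney taken cannot be told apart with so few libraries. A lower share of tubule cells could raise all non-tubule lists and lower the tubule lists. The tubule lists were split, with median log2 fold changes of 0.52 for proximal tubule markers and -0.16 for loop of Henle markers. For distal tubule and collecting duct markers the median was -0.20. The matrix and immune scores were higher than the mean of the endothelial, mural and podocyte scores by 0.23 more in SiNP (exact p = 0.405). A lower share of tubule cells therefore stays open as well.

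The third pattern is the difference in clock genes. Of 100 splits, 1, the real split, gave 4 clock genes adjusted over the list alone, and the highest of the others gave 3. The clock list was singled out among 29 after its values were seen, and this count was not made for the other lists. The splits therefore do not exclude chance. Without both libraries with Y-linked counts the 4 log2 fold changes kept at least 0.88 of their values, each with an unadjusted edgeR p under 0.05. Each group held 1 of these libraries, so this fit was bound to change little and is no test of sex. Without the 3 libraries poor in inner medulla the fold changes kept at least 0.86, again each with an unadjusted edgeR p under 0.05. The differences thus did not rest on those 3 libraries alone, and other differences in the part of the kidney stay open. The bound on the unadjusted p was set with these fits known. With a call of Cry1 as the bound, those 3 libraries would stay open as well. Its call ended in both smaller fits, at log2 fold changes of -1.93 (SE 0.22) and -1.70 (SE 0.22) against -1.83 (SE 0.19). Collection at another hour in the SiNP group may give such a pattern. Of 9 other clock genes, 5 lay in the direction of a later hour. These 9 are not all of the other tested clock genes, and they were chosen after the results had been seen. The count therefore decides nothing. The labels give no hour, so time of day and treatment cannot be told apart.

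Counts of called genes were also set against the 100 splits. As many genes as the real 1 were called in 11 of them, and the highest other split called 246, so chance is not excluded. The same 11 splits stand for genes lower (real 1, highest other 156) and for genes changed at least 2-fold (real 1, highest other 67). At an unadjusted p under 0.05, as many genes as the real 1374 were found in 14 splits, with up to 3701 in another, so chance is not excluded for that number. For genes higher the real count is 0, so all 100 splits reach it and the comparison says nothing (highest other 90). Camera called at least the real 9 lists in 71 splits, with up to 15 in another, so chance is not excluded for that count either. The unfolded protein response list had as small a p in 51 splits and the apoptosis list in 45 (real values 0.253 and 0.681, smallest of the others 7.7e-04 and 0.199, by permutation of the libraries). The split with 246 genes set saline 2, 3, 4 and 5 and SiNP 1 against the rest, and one with 82 genes set saline 2, 4 and 5 and SiNP 1 and 5 against the rest. Such counts point to a structure of the libraries. The splits with 246 and 82 genes both set saline 1, SiNP 2 and SiNP 4, the libraries poor in inner medulla transcripts, on the same side. The split with 246 genes differs from the treatment groups by a swap of saline 1 and SiNP 1 alone. What drives these splits was not tested.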

How the results depend on the processing

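The sex term, the inner medulla covariate, the fits without sets of libraries, mitochondrial genes or robust estimation, and, for lists other than the unfolded protein response and apoptosis, every alternative to camera but the estimated correlation were chosen after seeing the data. The unfolded protein response and apoptosis lists stayed uncalled by camera in every alternative, with adjusted p from 0.181 to 0.914 and from 0.588 to 0.955. The direction turned for the unfolded protein response list without the 3 libraries poor in inner medulla (0.905), and for apoptosis with limma on FPKM and a minimum mean FPKM (0.905 with a pseudocount of 1 and 0.924 with 0.1). The cause was not tested. The DESeq2 Wald test called 81 genes, 60 higher, 21 lower and 69 at 2-fold, against 1, 0, 1 and 1 with edgeR. It made more false calls in simulated counts, whose dispersions were edgeR estimates.

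With the replicate block 0 genes were called, 0 lower and 0 at 2-fold, and Cry1 had an adjusted p of 0.546. The labels do not say whether the numbers pair the libraries. To look for pairs, each gene's group mean was taken off its log2 CPM, and these deviations were correlated between the groups. Same-numbered libraries had correlations of -0.46, -0.09, 0.18, -0.12 and 0.58, and 3 of 10 libraries correlated best with their own number. Saline 5 and SiNP 5, which alone held Y-linked counts, correlated best with each other. Low correlations of such deviations over all genes cannot exclude a pairing. The block changed no call of the unfolded protein response or apoptosis list (adjusted p = 0.412 and 0.835), left 9 lists called, and gave 0 list scores by sign flips, whose smallest exact p of 0.0625 allows no call.

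Leaving out 1 library gave 0 to 3 called genes, 0 to 2 higher, 0 to 1 lower and 0 to 3 at 2-fold, with fewer libraries in each fit. The sex term gave 2 genes, Cry1 and Nr1d2, 1 higher, and 2 at 2-fold. Without both libraries with Y-linked reads 0 were called, 0 lower and 0 at 2-fold. Without the 3 libraries poor in inner medulla there were 2, 2 higher, 0 lower and 2 at 2-fold. The 9 called lists became 0 with an estimated correlation and 0 with fry one way, and 6 to 10 in the other settings. No list score passed in any setting, which says little. With 29 lists a call needs at least 5 at the smallest exact p of 0.00794, or more at a larger p. In the fits without 2 or 3 libraries 17 must reach the smallest exact p of 0.0286. RLE and upper-quartile scaling moved the median of all genes by 0.01 and 0.03.

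Of 87 named genes, 25 uncalled by edgeR were called by DESeq2, and Cry1 was called in 16 of 26 settings. Signs turned only for uncalled genes. Over fits without 1 library, log2 fold changes ran from -0.20 to 0.081 for Ddit3, -0.037 to 0.12 for Atf4, -0.32 to 0.013 for Eif2ak3, -0.34 to 0.13 for Bcl2, -0.39 to 0.76 for Havcr1 and -0.70 to 0.82 for Lcn2. Without the Y-positive libraries Ddit3 was at 0.0064, Havcr1 at -0.63 and Lcn2 at 1.15. Without the medulla-poor libraries Kdr was at -0.11, Ddit3 at 0.029, Eif2ak3 at 0.038 and Lcn2 at 0.28. Lcn2 was also at 0.49 with limma voom, 0.10 with the block and 0.36 with the sex term. At this depth, genes under about 1 CPM rest on fewer than 20 counts per library.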

Other observations

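All fits and genes in this part were chosen after the values were seen. Each group held 1 library that differed from the rest in sex-linked transcripts. Saline 5 and SiNP 5 had 2820 and 2898 counts of Y-linked genes and 0 counts of the XIST intron feature, and the other 8 libraries had 0 Y-linked counts and 319 to 792 of that feature. Slco1a1, an organic anion transporter, was at 349 and 441 CPM in these 2 libraries and at most 0.11 CPM elsewhere. Cyp2c11, a male-specific cytochrome in rat liver, was at 22.3 and 34.5 CPM and 0 elsewhere, and Cyp4b1 was at 29.4 and 9.78 CPM against 167 to 681 CPM elsewhere. The labels give no sex. The first 2 principal components held 31.0% and 23.8% of the variance, and saline 5 and SiNP 5 had the highest values on the second. On the first, SiNP 2, SiNP 4 and saline 1, the libraries poor in inner medulla transcripts, had the lowest values (-81.5, -45.5 and -43.4).

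The libraries also differed in transcripts of kidney regions, within both groups. Slc14a2, the urea transporter of the inner medulla, was at 0 CPM in saline 1, 0.46 in SiNP 2 and 0.16 in SiNP 4, and from 74.9 to 645 CPM in the other 7.

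Without both libraries with Y-linked reads, the matrix list had a mean log2 fold change of 1.15 in 20 genes and the immune list one of 1.02 in 16 genes. Their camera adjusted p with an estimated correlation was 0.0520 and 0.0709, against 0.727 for both with all 10 libraries. This fit leaves out SiNP 5, which had the lowest SiNP score in both lists (-0.55 for matrix and -0.51 for immune). A larger difference without it says nothing on sex. With a sex term and all libraries the means were 0.74 for matrix and 0.66 for immune, against 0.80 and 0.65 without the term.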
